A study of Caenorhabditis elegans with 16 samples.

How the data were processed

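Messenger RNA of whole C. elegans of the N2 Bristol strain was measured in 16 libraries, 4 each from young adults fed freely, young adults fasted for 6 h, day 8 adults fed freely and day 8 adults fasted for 6 h. Per the labels' protocols, animals were kept on NGM plates at 20 °C, snap frozen in Qiazol, extracted with an RNeasy Mini kit, and polyA RNA libraries were made with the Kapa mRNA HyperPrep kit. The labels number the libraries 1 to 4 in each group and do not say whether these are separate cultures, so each p-value measures only the spread between these libraries. The well codes in the sample names put all young libraries in 1 plate column and all day 8 libraries in another, so plate column and age cannot be told apart.

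The deposited table holds expected counts per gene, a name given here from the values: they are not whole, they differ in total between libraries, and 94.6 to 96.7% of the values up to 12 lie within a share of 0.06 of a whole number. The submitters' processing notes list the tool name DESeq and the genome build WBcel235, and the aligner, the counter and their versions are not given in the sources used here. Even values are in excess, at 57.0 to 68.2% of values between 1 and 12, as read pairs counted at both ends would give, so counts divided by 2 were tried as an alternative. The table has 21882 genes, of which 202 are at 0 in all libraries. Gene symbols, positions and types came from the WBcel235 annotation, release 115, which held 21714 of the gene IDs. It gave a symbol for 19626 of them. Whether the counting used strand is not stated, so genes that overlap a neighbour on the other strand are uncertain, and counts of near-identical copies (major sperm proteins, histones, vitellogenins, small heat shock proteins) may have been split between copies.

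Totals ranged from 58.4 to 117.7 M counts per library (M, counts in units of 1e6). Counts were rounded, genes were filtered with filterByExpr on the 4 groups (17844 kept, 4038 removed) and libraries were scaled with TMM factors. Levels are given as CPM (counts per 1e6 counts) after this scaling, as mean ± SD over 4 libraries. All 16 libraries entered 1 model with a mean per group in edgeR 4.0.16 under R 4.3.3. The spread of each gene was estimated over all 16 libraries, so tests in young adults take in the spread at day 8 and the reverse. Differences were tested with the quasi-likelihood test and adjusted over the tested genes with the Benjamini-Hochberg method, with a call at an adjusted p under 0.05. Log2 fold changes are given with an SE derived from the quasi-likelihood F. The 5 contrasts were fasted over fed in young adults, fasted over fed at day 8, the difference between these responses (young minus day 8), and day 8 over young in fed and in fasted animals. This design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

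For 48 lists of related genes with at least 4 tested members, limma 3.58.1 camera compared each list with all other genes on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists and the 5 contrasts. The same was done for 155 families of genes that share a symbol prefix and have at least 10 tested members. A list p named "with an estimated correlation" comes from camera with the correlation estimated from the residuals, a stricter setting. These residuals come from all 16 libraries around their group means, so they hold the split among day 8 libraries described below. This is so for the young fasting contrast too, and how far the split raises these p-values was not tested. The directional test fry was a further alternative. List members were counted from the gene test, and also "adjusted over the list alone".

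Named genes followed a fixed rule. For each contrast it took, among called genes with a lettered symbol (letters, a hyphen and a number), a mean of at least 10 CPM in the higher group and no overlap between the libraries compared, the 10 with the largest rise and the 10 with the largest fall. It added up to 4 members of each list discussed, those with the smallest adjusted p, and 20 genes named whether or not they passed. Genes outside this rule are said to have been chosen after their values were seen.

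Each step was tested on simulated counts with means taken from the data and with 200 genes changed. For the young fasting contrast edgeR recovered 22.1%, 60.6% and 93.9% of the genes changed by 0.5, 1 and 2 on the log2 scale, and 0.847% of its calls were false. For the day 8 fasting contrast these shares were 20.6%, 60.6% and 90.9%, with 5% false calls. For the difference between the responses they were 5.88%, 28.8% and 78.8%, with 2.6% false calls. In the age contrasts 8.67% of calls were false for fed and 11.9% for fasted animals, above the nominal level. All such shares, here and below, describe the simulated counts. They may not hold for the real libraries. The simulations for both fasting contrasts and their difference carried the split among day 8 libraries described below, as separate means. Those for the age contrasts used the same mean for all libraries, and so lacked this split.

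Same-numbered libraries were checked for pairing from the correlation of their deviations from the group means. Between fed and fasted day 8 animals the 4 same-numbered pairs had correlations of 0.421, 0.55, 0.329 and 0.564, so the numbers pair these libraries by the rule used (all over 0.1). Other-numbered libraries of the same set (1 and 2, or 3 and 4) correlated as highly, up to 0.666, only 4 of the 8 libraries correlated best with their own number, and across sets correlations ran from -0.587 to -0.375. The pairs therefore follow the sets and cannot be told from them. In young adults the same-numbered correlations ran from -0.005 to 0.04, so the numbers do not pair these libraries by the rule used. Of the 8 young libraries 6 still correlated best with their own number, and other-numbered correlations reached 0.017. At day 8, libraries 1 and 2 stood apart from libraries 3 and 4 in both feeding states. The biological coefficient of variation was 5.82% in the young and 33.8% in the day 8 libraries, and 14% in the latter with a term for these sets. Whether libraries within a set share a source is not stated.

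Alternatives were DESeq2 1.42.0, other scaling factors (RLE, upper quartile, TMM without germline, embryo and yolk genes), no low-count filter, a filter at 5 CPM in 4 libraries, the replicate number as a block, a minimum absolute log2 change of 1, fits on the 8 libraries compared and leaving out each library in turn. Added after seeing the data were a block within each age, a term for day 8 libraries 3 and 4, either set of day 8 libraries alone, the 2 libraries of each set summed, a block with only the 8 libraries compared, counts divided by 2, removal of a pseudogene beside the ribosomal RNA genes, and limma voom with sample quality weights. No sample column of the table was left out.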

Results

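Gene expression was measured by RNA sequencing in whole young adult and day 8 C. elegans, each either fed or fasted for 6 h, with 4 libraries in each of the 4 groups. Per the series description, the aim was to find genes that fasting induces or represses in young but not in aged animals. Libraries held 76.9 to 90.4 M counts (M, counts in units of 1e6) in fed young adults, 58.4 to 78.4 M in fasted young adults, 80.7 to 117.7 M in fed day 8 animals and 65.2 to 75.4 M in fasted day 8 animals. Between 18215 and 20764 genes had a count above 0.

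Age was the main axis of variation, followed by feeding in young adults. The first principal component held 77.7% of the variance and separated the ages, and the second (9.4%) separated fed from fasted young adults. The third (5.07%) separated day 8 libraries 1 and 2 from day 8 libraries 3 and 4, whatever their feeding state.

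**Figure D1:**
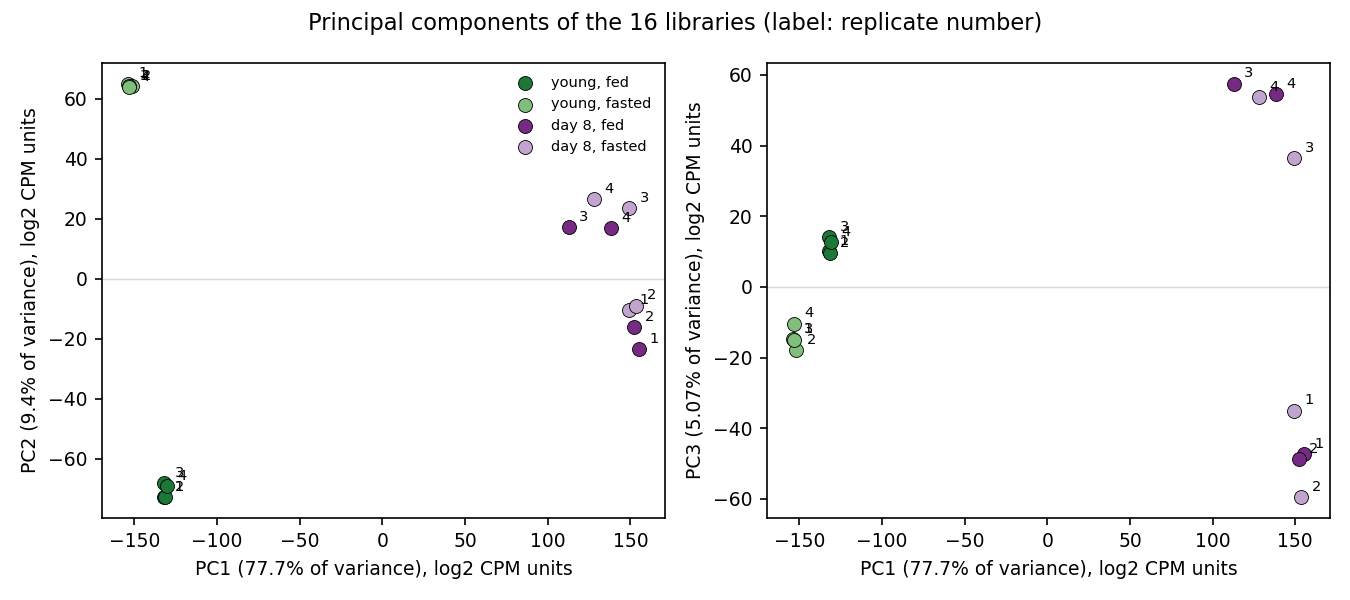
Principal components of log2 CPM for the 16 libraries, each point a library labelled by its replicate number and coloured by group, with component 2 (left) and component 3 (right) against component 1. Fed and fasted young adults separate on component 2 (9.4% of variance), while day 8 libraries separate by number on component 3 (5.07%).

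In young adults, 6 h of fasting raised the acyl-CoA synthetase gene acs-2 and the glyoxylate cycle gene icl-1 and lowered the desaturase gene fat-7. The level of acs-2 (WBGene00009221, chromosome V, 15567394 to 15569897) stood at 10.9 ± 1.25 CPM in fed and 833 ± 21.8 CPM in fasted animals (SD, n = 4), a log2 fold change of 6.26 ± 0.12 (SE, adjusted p = 4.11e-15). That of icl-1 (WBGene00001564, chromosome V, 724332 to 728004) went from 128 ± 5.13 to 4459 ± 34.3 CPM (log2 5.12 ± 0.12, adjusted p = 5.16e-14). Conversely, fat-7 (WBGene00001399, chromosome V, 7151353 to 7153146) fell from 250.4 ± 5.01 to 5.17 ± 0.201 CPM (log2 -5.60 ± 0.22, adjusted p = 2.15e-11). In all, 3790 genes rose and 3767 fell of 17844 tested, and 7275 of these 7557 showed no overlap between the 4 fed and 4 fasted libraries.

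Among called genes with a lettered symbol, at least 10 CPM in the higher group and no overlap between libraries, the largest rises in young adults were those of cyp-37B1 (log2 9.02 ± 0.28), the flavin monooxygenase fmo-2 (8.46 ± 0.38), the lysosomal lipase lipl-3 (8.13 ± 0.38), the acyltransferase-like oac-14 (6.79 ± 0.25), the carnitine palmitoyltransferase cpt-3 (6.70 ± 0.41), cyp-32B1 (6.50 ± 0.29), the metallothionein mtl-1 (6.36 ± 0.36), acs-2, clec-76 (5.81 ± 0.47) and ptr-22 (5.75 ± 0.47). Fed levels of several were close to 0, with fmo-2 (WBGene00001477) at 0.951 ± 0.291 CPM and lipl-3 (WBGene00020016) at 0.197 ± 0.114 CPM. Within the same limits the largest falls were those of the folate transporter folt-2 (-7.08 ± 0.35), spp-23 (-6.54 ± 0.41), irg-8 (-6.13 ± 0.39), pho-13 (-6.09 ± 0.40), fat-7, the yolk protein gene vit-1 (-5.48 ± 0.22), dod-19 (-5.36 ± 0.15), vit-4 (-4.99 ± 0.33), ugt-63 (-4.82 ± 0.26) and hrg-7 (-4.55 ± 0.29). Adjusted p for these 20 genes lay at or below that of ptr-22, 8.3e-08.

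Peroxins rose in fasted young adults, and peroxisomal enzymes moved both ways. Of 11 peroxins, the factors of peroxisome assembly and import, 6 rose and 5 were not called (7 higher and 1 lower adjusted over the list alone), with prx-11 at 2.57 ± 0.19, prx-6 at 1.29 ± 0.09, prx-2 at 1.21 ± 0.14 and the import receptor prx-5 at 1.12 ± 0.11. The camera test gave adjusted p = 0.00175, and adjusted p = 0.121 with an estimated correlation. Among 21 peroxisomal enzymes and transporters 14 rose and 7 fell, and the same numbers held adjusted over the list alone. The list had adjusted p = 0.0181, and adjusted p = 0.322 with an estimated correlation. The acyl-CoA oxidase gene acox-3 (2.61 ± 0.12), the protease lonp-2 (1.91 ± 0.10) and the catalase ctl-2 (1.74 ± 0.09) rose, whereas acox-1.4 (-3.33 ± 0.11) and acox-1.2 (-1.23 ± 0.07) fell. The thiolase daf-22 rose by 1.13 ± 0.15, and prx-10 by 0.53 ± 0.11.

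Lipases and autophagy genes rose with them. Of 12 lipases 7 rose and 5 were not called, over all genes and adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.117 with an estimated correlation), among them lipl-3, lipl-2 (5.23 ± 0.53), fil-1 (4.70 ± 0.32) and lipl-1 (4.00 ± 0.47). Of 26 autophagy genes 14 rose and 1 fell, also adjusted over the list alone, with lgg-1 at 1.75 ± 0.09, atg-2 at 1.73 ± 0.07, epg-9 at 1.66 ± 0.06 and lgg-2 at 1.39 ± 0.06. This list passed with an adjusted p = 0.000157, and alone of the 48 lists it also passed in this contrast when the correlation was estimated (adjusted p = 0.0317 with an estimated correlation). Regulators of metabolism rose in 13 of 29 cases and fell in 1, the same adjusted over the list alone (adjusted p = 0.00509, and adjusted p = 0.213 with an estimated correlation), led by hlh-30 (1.26 ± 0.07), crtc-1 (1.70 ± 0.11), the insulin receptor gene daf-2 (1.2 ± 0.10) and the AMPK subunit aak-2 (0.46 ± 0.06). The receptor gene nhr-49 rose by 0.38 ± 0.05. Genes described as raised by DAF-16 rose in 10 of 15 cases (10 higher and 2 lower adjusted over the list alone; adjusted p = 3.83e-06, and adjusted p = 0.17 with an estimated correlation), including nnt-1 (5.10 ± 0.24) and hil-1 (2.81 ± 0.13).

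Mitochondrial fatty acid oxidation did not move one way. Of 20 such genes 9 rose and 7 fell (11 and 7 adjusted over the list alone; adjusted p = 0.203), with acdh-7 at 1.25 ± 0.05 and ech-7 at -2.99 ± 0.13. Of 20 genes of fatty acid synthesis 10 fell and 5 rose, the same adjusted over the list alone. As a list this gave adjusted p = 0.0296, and adjusted p = 0.257 with an estimated correlation. The elongases elo-5 (-3.76 ± 0.06), elo-2 (-3.25 ± 0.10) and elo-6 (-3.10 ± 0.10) fell, while the desaturases fat-5 (1.52 ± 0.13) and fat-6 (0.29 ± 0.07) rose. Propionate and vitamin B12 genes fell in 10 of 13 cases and rose in 1, the same adjusted over the list alone, with acdh-1 at -3.72 ± 0.24, ech-6 at -2.21 ± 0.07 and hphd-1 at -1.84 ± 0.08. Camera gave adjusted p = 0.000147, and adjusted p = 0.22 with an estimated correlation.

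Genes of lysosomal acidification, respiration and the proteasome were lower in fasted young adults. Lysosomal genes fell in 17 of 28 cases and rose in 4 (17 and 5 adjusted over the list alone), and the named members are subunits of the proton pump: vha-11 (-1.38 ± 0.05), vha-8 (-1.16 ± 0.06), vha-10 (-1.1 ± 0.05) and vha-4 (-1.07 ± 0.05). The list gave adjusted p = 4.08e-07, and adjusted p = 0.0797 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 34 of 64 cases (36 adjusted over the list alone) by a median of -0.21, for example ucr-2.2 at -0.88 ± 0.08 and gas-1 at -0.68 ± 0.06. The list test gave adjusted p = 1.54e-06, and adjusted p = 0.602 with an estimated correlation. Proteasome genes fell in 25 of 33 cases and rose in 1 (29 and 1 adjusted over the list alone), with pbs-5 at -0.53 ± 0.08. For the list camera gave adjusted p = 3.29e-05, and adjusted p = 0.699 with an estimated correlation. Oocyte genes fell in 14 of 25 cases (17 adjusted over the list alone) by a median of -0.50, for example oma-2 at -0.93 ± 0.21 (adjusted p = 0.00034, and adjusted p = 0.701 with an estimated correlation). Of 6 vitellogenins 3 fell (3 adjusted over the list alone), vit-1, vit-4 and vit-3 (-3.93 ± 0.40), while the abundant vit-2 stood at 29710 ± 201.8 CPM fed and 27950 ± 480.8 CPM fasted (-0.09 ± 0.14, adjusted p = 0.621). Fed and fasted young libraries did not overlap for vit-2, and its SE takes in the spread at day 8 (SD 2572 CPM fed and 1428 CPM fasted). The vitellogenin list gave adjusted p = 0.00345, and adjusted p = 0.22 with an estimated correlation. Among 131 neuropeptide genes 75 rose and 10 fell (80 and 10 adjusted over the list alone), with nlp-25 at 4.09 ± 0.37 and flp-10 at 1.33 ± 0.13. Tested as a list they gave adjusted p = 3.12e-07, and adjusted p = 0.434 with an estimated correlation.

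Few of the mitochondrial dynamics and stress markers named in advance were called in young adults. The fission gene drp-1 had a log2 fold change of -0.32 ± 0.12 (adjusted p = 0.0445), a call that ended when any 1 of the 8 young libraries was left out (adjusted p 0.0516 to 0.0906). Its levels did not overlap between fed (177.6 ± 2.90 CPM) and fasted (141.8 ± 2.04 CPM) young libraries. The model estimates 1 spread per gene over all 16 libraries, so the day 8 SD of drp-1 (34.3 fed, 34.2 fasted) enters its SE. Values for the fusion gene fzo-1 (-0.12 ± 0.09, adjusted p = 0.266), sod-3 (-0.14 ± 0.22, adjusted p = 0.629) and hsp-6 (-0.02 ± 0.13, adjusted p = 0.899) did not pass. The fzo-1 levels, too, did not overlap between fed (110.8 ± 0.878 CPM) and fasted (101.8 ± 1.53 CPM) young libraries, while those of sod-3 and hsp-6 overlapped. The low-expressed lipl-4 rose by 1.73 ± 0.38, from 0.724 ± 0.269 to 2.41 ± 0.3 CPM.

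**Figure D2:**
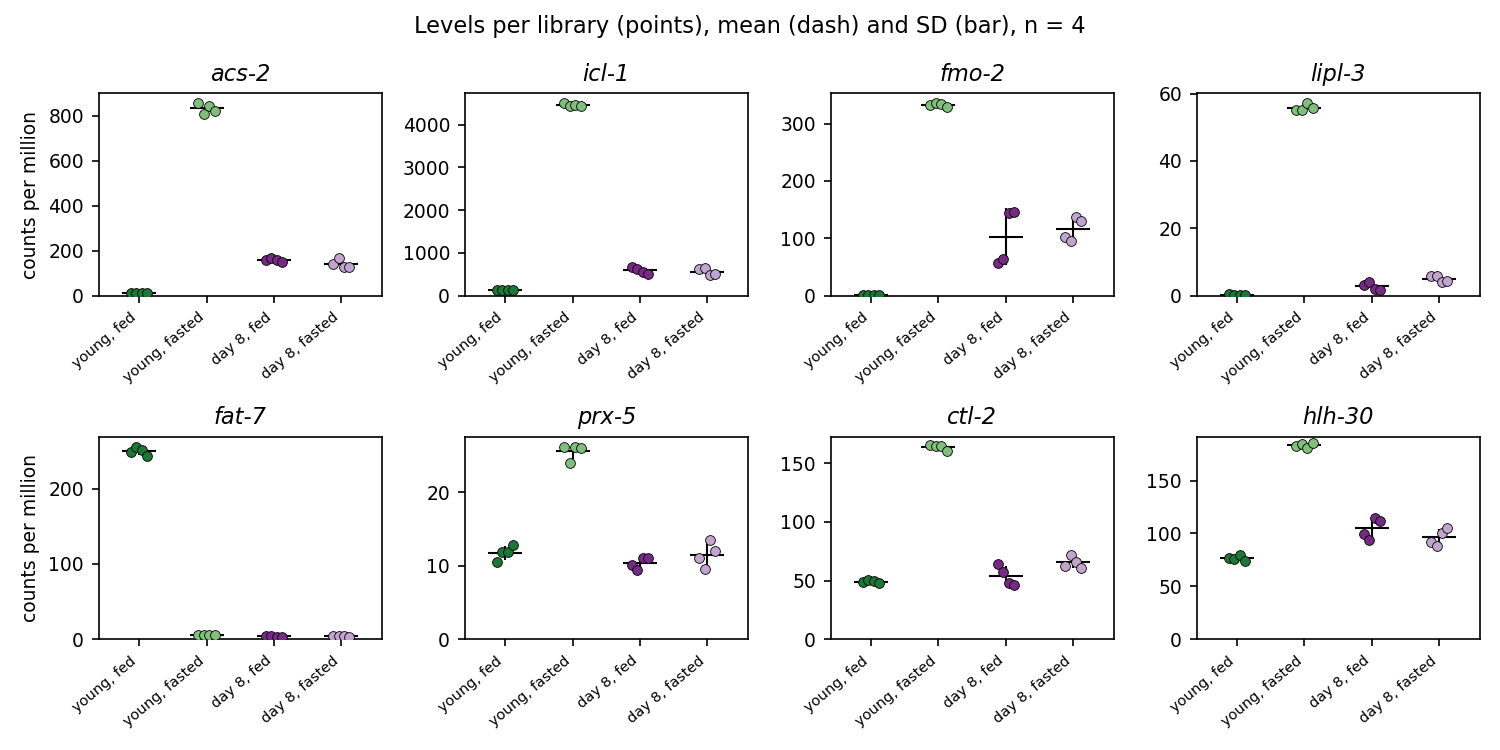
Counts per M of 8 genes in each library, with points for libraries, a dash for the mean and a bar for the SD over 4 libraries per group, on axes from 0. In acs-2, fed young adults average 10.9 CPM, fasted young adults 833, fed day 8 animals 158 and fasted day 8 animals 141.

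At day 8, few genes were called after the same fast, and acs-2, icl-1 and fmo-2 were not among them. Fed day 8 animals held acs-2 at 158 ± 7.5 CPM and fasted ones at 141 ± 19 CPM (SD, n = 4; log2 -0.17 ± 0.09, adjusted p = 1). In these animals icl-1 stood at 587 ± 74.6 and 561 ± 78.1 CPM (-0.07 ± 0.10, adjusted p = 1), and fmo-2 at 103 ± 49.2 and 116 ± 20.4 CPM (0.17 ± 0.27, adjusted p = 1). Of 17844 genes, 27 rose and 39 fell in edgeR, with 927 at an unadjusted p under 0.05, and DESeq2 called 98 higher and 129 lower. On simulated counts 5% of day 8 calls were false in edgeR and 19.5% in DESeq2.

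Named falls at day 8 were those of semo-1 (log2 -1.32 ± 0.13), cyp-35C1 (-1.08 ± 0.16), dod-19 (-1.01 ± 0.12), the collagens col-143 (-1.0 ± 0.10), col-101 (-0.98 ± 0.11) and col-95 (-0.66 ± 0.11), hphd-1 (-0.81 ± 0.08), the lectin clec-150 (-0.81 ± 0.13), the carbonic anhydrase cah-4 (-0.65 ± 0.05) and the gluconeogenic enzyme pck-1 (-0.57 ± 0.11). Besides histones, the named rises were ilys-2 (0.96 ± 0.19), pud-2.2 (0.95 ± 0.17) and the peroxisomal protease lonp-2 (0.47 ± 0.10, adjusted p = 0.0497), whose call ended under other scalings (RLE adjusted p = 0.0591). With only the 8 day 8 libraries in the fit, edgeR called no gene higher and 4 lower. No rise named at day 8, histones included, kept its call in that fit. Propionate and vitamin B12 genes fell in 2 of 13 cases, hphd-1 and alh-8 (-0.37 ± 0.06), and in 4 adjusted over the list alone. The list had adjusted p = 2.18e-06, and adjusted p = 0.134 with an estimated correlation. Detoxification genes fell in 5 of 177 cases (2 higher and 11 lower adjusted over the list alone), among them ugt-63 (-1.84 ± 0.23), ugt-7 (-1.21 ± 0.17) and ugt-58 (-0.41 ± 0.05), and the list did not pass (adjusted p = 0.3). Collagens fell in 4 of 160 cases (1 higher and 13 lower adjusted over the list alone), the remaining member being col-179 (-0.92 ± 0.17; adjusted p = 3.47e-07, and adjusted p = 0.608 with an estimated correlation). In the methionine list, the cystathionine gamma-lyase cth-1 rose by 1.22 ± 0.11.

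Of 21 peroxisomal enzymes 1 rose, lonp-2, and 20 were not called (6 higher and 1 lower adjusted over the list alone). At an unadjusted p under 0.05, 8 were higher and 1 lower, and DESeq2 called 2 higher and 1 lower. The list passed upward with a median of 0.14 (adjusted p = 0.000833, and adjusted p = 0.17 with an estimated correlation). No peroxin of 11 was called by edgeR or by DESeq2 at day 8, with 1 higher at an unadjusted p under 0.05. The peroxin list nevertheless passed camera upward, with a median of 0.15 (adjusted p = 0.00186, and adjusted p = 0.121 with an estimated correlation), prx-6 standing at 0.22 ± 0.09 and prx-5 at 0.15 ± 0.11. Among 26 autophagy genes none was called by either tool, 1 was lower at an unadjusted p under 0.05, and the list did not pass (adjusted p = 0.921). Of 12 lipases edgeR called none, with 1 higher at an unadjusted p under 0.05 and 1 called higher by DESeq2 (adjusted p = 0.647 for the list). The values of lipl-4 (0.66 ± 0.38), fat-5 (0.43 ± 0.13), fat-6 (-0.17 ± 0.07), fat-7 (0.22 ± 0.19), nhr-49 (0.00 ± 0.05), hlh-30 (-0.12 ± 0.07), prx-10 (0.18 ± 0.11), daf-22 (0.20 ± 0.15), acox-1.2 (-0.07 ± 0.07), ctl-2 (0.28 ± 0.09), drp-1 (-0.06 ± 0.12), fzo-1 (-0.04 ± 0.09), vit-2 (-0.21 ± 0.14), sod-3 (0.16 ± 0.23) and hsp-6 (-0.08 ± 0.13) did not pass.

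By the rule used, the same-numbered day 8 libraries form pairs, and the lipase gene lipl-3 was higher in the fasted library of all 4, at 3.24 and 5.83, 4.09 and 5.90, 1.95 and 4.12, and 1.72 and 4.32 CPM fed and fasted. Its log2 fold change was 0.88 ± 0.27 (adjusted p = 0.363 without a block, 0.19 with the replicate block, 0.00829 with a block within each age, 0.0257 with a block in the 8 day 8 libraries alone). With the 2 libraries of each set summed, adjusted p was 1. Also higher in all 4 pairs were prx-5, prx-10 and lipl-4, and lower in all 4 were fat-6, hlh-30 and drp-1. With a block within each age fat-5 (adjusted p = 0.0341), fat-6 (0.0339), ctl-2 (0.0339) and prx-10 (0.0488) passed too, a fit in which 37.7% of day 8 calls on simulated counts were false. None of these 4 passed with the replicate block, with a block in the 8 libraries, or with the libraries of each set summed (adjusted p = 0.231, 0.92, 0.582 and 1 in the same order).

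Histone genes were higher in fasted than in fed day 8 animals. Of 55 histone genes 9 rose (36 adjusted over the list alone) by a list median of 1.22, with his-17 at 2.07 ± 0.41, his-8 at 1.93 ± 0.36, his-6 at 1.84 ± 0.31 and his-12 at 1.82 ± 0.33. As a list this gave adjusted p = 8.07e-36, and adjusted p = 0.0317 with an estimated correlation. Within the limits of symbol, level and overlap, a further 2 of the largest rises were histone genes whose symbols belong to more than 1 gene. The pseudogene WBGene00004677, which lies beside the ribosomal RNA genes on chromosome I (15060299 to 15061150), took 1.78 ± 1.01% of counts in fed and 5.28 ± 2.62% in fasted day 8 libraries (n = 4 each, two-sided exact permutation p = 0.0571). In young adults it took 3.70 ± 1.93% fed and 3.90 ± 1.79% fasted. With this share in the fit the histone median was 0.49 and the 9 histone calls ended.

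The day 8 count varied between fits: the 8 day 8 libraries alone gave no gene higher (edgeR, 419 genes at an unadjusted p under 0.05) and 4 lower, a term for libraries 3 and 4 gave 224 higher and 614 lower, and the 2 libraries of each set summed gave 7 higher and 29 lower. With the replicate block edgeR called 15 higher and 32 lower, or 167 and 347 with a block within each age.

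The response to fasting differed between the ages for 4650 genes, tested as the young minus the day 8 response. Of these, 2396 had a higher and 2254 a lower value in young adults. Within the limits of symbol, level and overlap, the largest positive differences were those of cyp-37B1 (log2 8.96 ± 0.33, adjusted p = 2.38e-11), fmo-2 (8.29 ± 0.45), lipl-3 (7.25 ± 0.45), oac-14 (6.67 ± 0.31), the lysozyme ilys-3 (6.64 ± 0.67), acs-2 (6.42 ± 0.14), cyp-32B1 (6.41 ± 0.35), clec-76 (6.4 ± 0.63), cpt-3 (6.27 ± 0.49) and ptr-22 (6.11 ± 0.58). Within them the largest negative ones were those of spp-23 (-7.01 ± 0.50), fat-7 (-5.82 ± 0.28), folt-2 (-5.53 ± 0.42), pho-13 (-5.53 ± 0.49), irg-8 (-5.48 ± 0.47), vit-1 (-5.08 ± 0.27), dod-19 (-4.35 ± 0.19), hrg-7 (-4.16 ± 0.37), vit-4 (-4.14 ± 0.40) and the protease pcp-2 (-4.08 ± 0.29). Some of these genes stood at or past the fasted young level in fed day 8 animals already. Fed day 8 and fasted young means were 41.9 and 11.9 CPM for ptr-22, 18.8 and 4.68 for ilys-3, and 3.45 and 5.17 for fat-7. They were 304 and 290 CPM for vit-1, and 463 and 451 for vit-4. The other genes of both rankings had not reached the fasted young level.

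Genes called in young but not in day 8 animals numbered 3767 that rose and 3736 that fell. With the difference itself also past the threshold, in the direction of a larger young response, 2261 rose and 2179 fell. Called at both ages in the same direction were 43 genes, against 14 if the calls were independent, 11 were called in opposite directions, and 12 were called at day 8 alone. Among those in the same direction were lonp-2, hphd-1, dod-19, folt-2 and ugt-63, and among those in opposite directions semo-1, higher in fasted young adults (0.32) and lower at day 8 (-1.32). Over the 7557 genes called in young adults, the log2 fold changes at the 2 ages had r = 0.272 and rho = 0.238 across genes, which are not independent replicates. The slope of day 8 on young values was 0.056, and 58% had the same sign. Leaving out 1 library gave r of 0.154 to 0.318, and over all 17844 tested genes r was 0.137. For the 343 genes that rose by 3 or more on the log2 scale in young adults, the median was 4.05 in young and 0.20 in day 8 animals. For the 165 that fell by as much, it was -3.64 and -0.26.

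**Figure D3:**
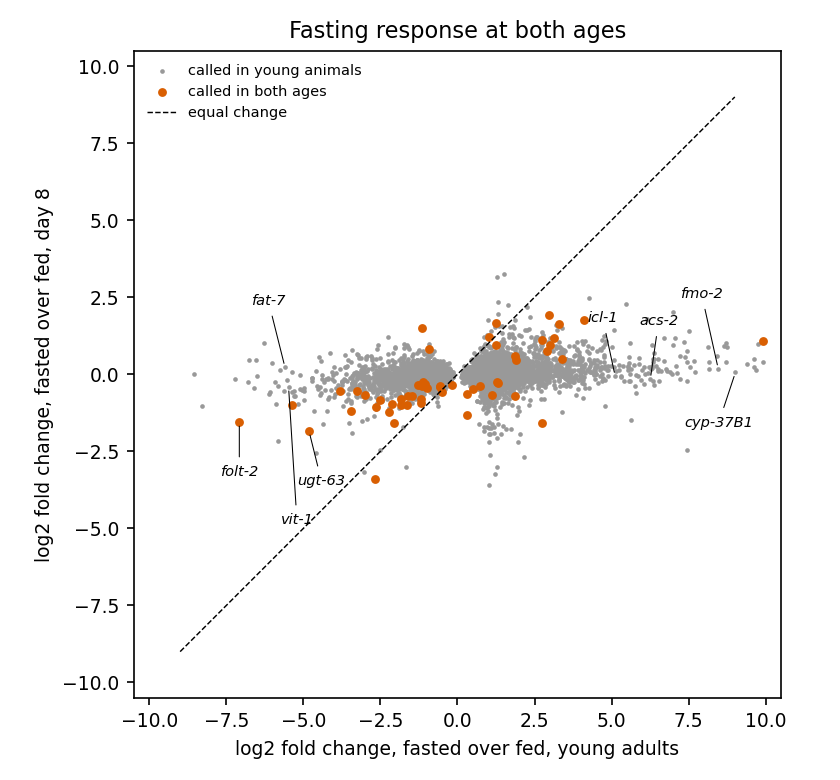
Log2 fold change of fasted over fed animals at day 8 (vertical) against young adults (horizontal) for the 7557 genes called in young adults, with genes called at both ages in orange and a dashed line of equal change. Points lie along the horizontal axis, with a slope of 0.056.

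Of the lists, 26 passed for the difference. Peroxins had a larger young value in 5 of 11 cases (5 adjusted over the list alone), led by prx-11 (2.27 ± 0.26), prx-6 (1.08 ± 0.12), prx-5 (0.98 ± 0.15) and prx-2 (0.93 ± 0.20). Camera gave adjusted p = 0.00509, and adjusted p = 0.17 with an estimated correlation. Peroxisomal enzymes were split, with 13 higher and 6 lower of 21 (14 and 7 adjusted over the list alone), acox-3 at 2.22 ± 0.16, ctl-2 at 1.46 ± 0.13, acox-1.2 at -1.16 ± 0.10 and acox-1.4 at -2.97 ± 0.14. The list test gave adjusted p = 0.0418, and adjusted p = 0.406 with an estimated correlation. Autophagy genes differed upward in 13 of 26 cases and downward in 1, the same adjusted over the list alone (epg-9 1.71 ± 0.09, atg-2 1.71 ± 0.10, lgg-1 1.70 ± 0.12, lgg-2 1.37 ± 0.09), and this list passed in both forms of the test. For the list camera gave adjusted p = 0.00011, and adjusted p = 0.0317 with an estimated correlation. Regulators differed upward in 11 of 29 cases (11 adjusted over the list alone), including crtc-1 (1.79 ± 0.16), hlh-30 (1.38 ± 0.10) and daf-2 (1.31 ± 0.14). Tested as a list they gave adjusted p = 0.000348, and adjusted p = 0.117 with an estimated correlation. Lysosomal genes differed downward in 17 of 28 cases and upward in 4, the same adjusted over the list alone, with vha-11 at -1.26 ± 0.07. The list had adjusted p = 4.09e-07, and adjusted p = 0.0797 with an estimated correlation.

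Histones passed for the difference without passing in young adults. They had a median of -0.06 in young adults (adjusted p = 0.596) and 1.22 at day 8, and the difference was lower for 19 of 55 and higher for 2 (25 and 3 adjusted over the list alone; adjusted p = 3.62e-05, and adjusted p = 0.409 with an estimated correlation). Collagens passed in young adults, where 22 of 160 fell and 9 rose (19 and 7 adjusted over the list alone; adjusted p = 0.0295, and adjusted p = 0.874 with an estimated correlation), and did not pass for the difference (adjusted p = 0.606).

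Of the remaining genes named in advance, icl-1 (5.18 ± 0.15), fat-5 (1.08 ± 0.18), daf-22 (0.92 ± 0.21), fat-6 (0.46 ± 0.10) and nhr-49 (0.38 ± 0.07) differed upward between the ages. No call was made for lipl-4 (1.07 ± 0.53, adjusted p = 0.155), prx-10 (0.35 ± 0.15, adjusted p = 0.0986), drp-1 (-0.26 ± 0.17), fzo-1 (-0.08 ± 0.12), vit-2 (0.12 ± 0.19), sod-3 (-0.31 ± 0.32) and hsp-6 (0.05 ± 0.19). Across the alternative fits, named genes gained a call for this contrast in 23 of 2011 cases, and no named call ended. Many of these genes were named for large or clear differences in the same data, so this says little on the other calls. Voom, for example, kept 1866 of the 2396 higher and 2047 of the 2254 lower calls. With a block within each age the counts were 4204 higher and 4847 lower, a fit in which 28.2% of calls for this contrast on simulated counts were false.

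**Figure D4:**
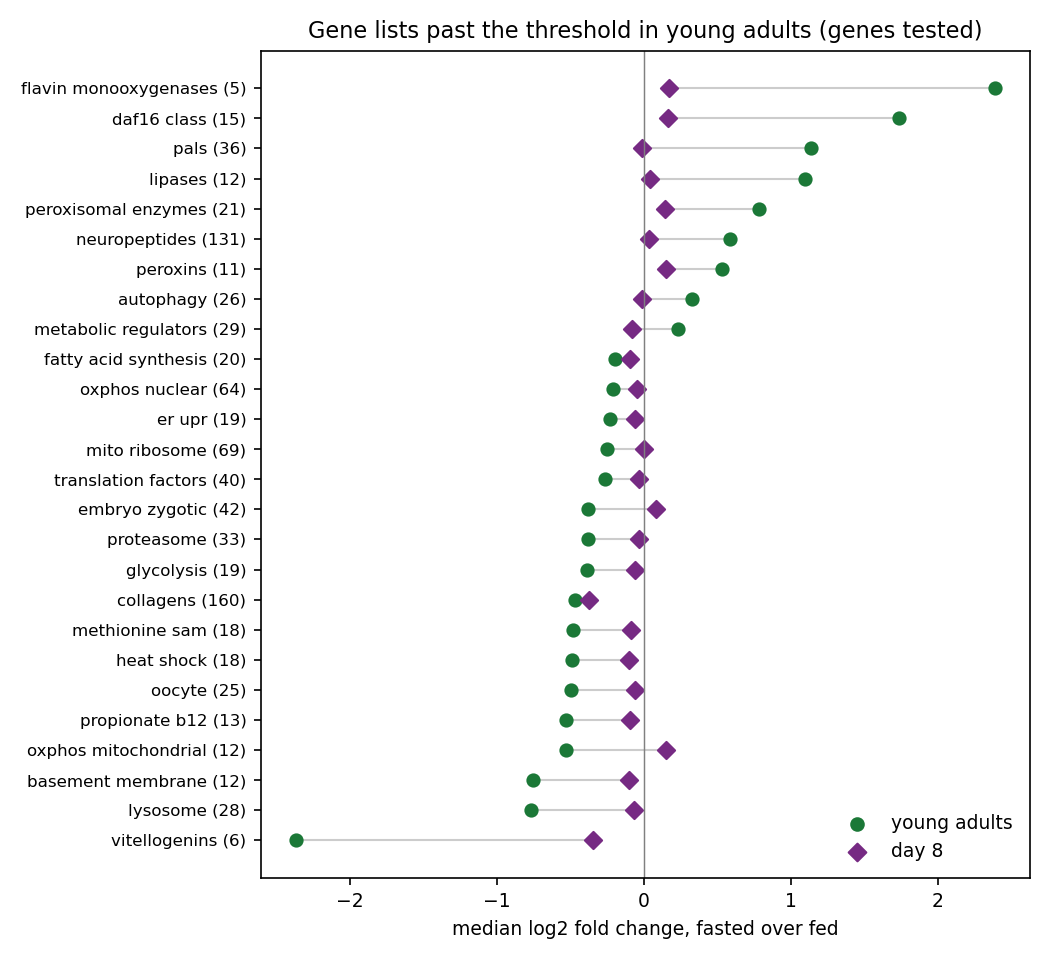
Median log2 fold change of fasted over fed animals for the 26 gene lists past the preset-correlation threshold in young adults, with circles for young adults, diamonds for day 8 and the number of tested genes in brackets. The autophagy list has a median of 0.32 in young and -0.01 in day 8 animals.

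Between young and day 8 fed animals, sperm, muscle, ribosome and respiration genes were lower and early-embryo and autophagy genes higher at day 8. The muscle genes pat-10 (log2 -3.90 ± 0.08), tni-3 (-3.77 ± 0.08), unc-27 (-4.23 ± 0.09) and unc-87 (-3.66 ± 0.10) stood for 21 of 22 body wall muscle genes that fell (21 adjusted over the list alone; adjusted p = 1.3e-09, and adjusted p = 0.328 with an estimated correlation). All 60 sperm genes fell in edgeR, over all genes and adjusted over the list alone, and DESeq2 called 24 of them lower. In this contrast DESeq2 gave no adjusted p for 116 of all tested genes, which count here as not called. How many of these are sperm genes was not examined. The median of the sperm genes was -7.93, and spe-11 fell by 5.02 ± 0.21. As a list this gave adjusted p = 2.43e-15, and adjusted p = 0.373 with an estimated correlation. Early embryonic genes rose in 29 of 42 cases and fell in 2 (30 and 2 adjusted over the list alone), with sdz-28 at 4.94 ± 0.24, sdz-14 at 4.44 ± 0.21 and sdz-9 at 3.77 ± 0.17. Camera gave adjusted p = 3.49e-08, and adjusted p = 0.0014 with an estimated correlation. Larval molting genes rose in 12 of 15 cases and fell in 2. Among them noah-1 stood at 9.04 ± 1.27 CPM in fed young and 145 ± 75.8 CPM in fed day 8 animals. In all, 5491 genes were higher and 6184 lower at day 8 (n = 4 and 4). This balance turned with RLE (6346 and 5679) and upper quartile (6781 and 5549) factors, with DESeq2 (6468 and 5664), and with no low-count filter (6423 and 5963) or a filter at 5 CPM (4334 and 4044). It also turned on leaving out any of day 8 libraries 3 and 4, fed or fasted.

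Within the limits of symbol, level and overlap, the largest rises with age in fed animals were those of the hatching protease hch-1 (10.91 ± 0.72), ilys-3 (9.22 ± 0.55), the linker histone hil-7 (8.78 ± 0.91), the insulin-like ins-2 (8.68 ± 0.73), clec-266 (8.40 ± 0.44), dpy-14 (8.06 ± 0.55), unc-39 (8.03 ± 0.57), fbxb-66 (7.97 ± 0.56), ptr-22 (7.56 ± 0.49) and hmg-6 (7.37 ± 0.56). Within them the largest falls were those of the collagens col-81 (-9.50 ± 1.27), col-139 (-9.23 ± 1.43), col-129 (-9.18 ± 1.32) and col-7 (-8.83 ± 1.06), of msd-1 (-9.19 ± 0.50) and of the major sperm proteins msp-55 (-9.0 ± 0.76), msp-45 (-8.80 ± 0.90), msp-113 (-8.78 ± 0.79), msp-50 (-8.54 ± 0.66) and msp-49 (-8.53 ± 0.65), whose near-identical copies make single values uncertain. Of the genes that fasting raised in young adults, 1425 were higher and 1355 lower with age in fed animals. Those higher included acs-2 at 3.86 ± 0.10, fmo-2 at 6.77 ± 0.36, lipl-3 at 3.78 ± 0.35 and icl-1 at 2.19 ± 0.11, and those lower included fat-5 and prx-2. The fasting-lowered fat-7 was lower with age (-6.19 ± 0.23).

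Genes of the cytosolic ribosome and of oxidative phosphorylation were lower at day 8 almost throughout. Mitochondrial fatty acid oxidation was not, with 7 of 20 genes higher and 8 lower, the same adjusted over the list alone (adjusted p = 0.6). Cytosolic ribosome genes fell in 78 of 80 cases and rose in 1, the same adjusted over the list alone, for example rpl-27 (-1.1 ± 0.07) and rps-17 (-0.99 ± 0.07). The list test gave adjusted p = 4.1e-16, and adjusted p = 0.447 with an estimated correlation. All 64 nuclear genes of oxidative phosphorylation fell, also adjusted over the list alone, asb-2 and asg-2 by 1.71 ± 0.06 and 1.71 ± 0.07. For the list camera gave adjusted p = 6.3e-15, and adjusted p = 0.374 with an estimated correlation. Glycolysis genes fell in 15 of 19 cases and rose in 1, the same adjusted over the list alone, gpd-2 by 2.73 ± 0.07. Tested as a list they gave adjusted p = 9.45e-05, and adjusted p = 0.322 with an estimated correlation. Propionate and vitamin B12 genes fell in 12 of 13 cases and rose in 1, the same adjusted over the list alone, with hphd-1 at -3.13 ± 0.08 and ech-6 at -2.69 ± 0.07. The list had adjusted p = 0.000288, and adjusted p = 0.22 with an estimated correlation. All 6 vitellogenins fell, also adjusted over the list alone, with vit-3 at -5.69 ± 0.44, vit-1 at -5.41 ± 0.21 and vit-2 at -1.29 ± 0.14. As a list this gave adjusted p = 0.00363, and adjusted p = 0.22 with an estimated correlation.

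Autophagy genes rose with age in fed animals, in 23 of 26 cases over all genes and adjusted over the list alone (adjusted p = 3.06e-08, and adjusted p = 0.00268 with an estimated correlation), with epg-2 at 4.09 ± 0.13 and atg-2 at 1.86 ± 0.07. Of the heat shock list 12 of 18 rose and 4 fell, the same adjusted over the list alone, hsp-16.41 by 4.89 ± 0.47 and hsp-16.2 by 4.69 ± 0.45, and the list did not pass (adjusted p = 0.109). Peroxins gave 2 higher and 4 lower of 11 (1 and 4 adjusted over the list alone; adjusted p = 0.64), with prx-11 at 0.95 ± 0.19 and prx-2 at -0.94 ± 0.14. Histones rose in 36 of 55 cases and fell in 4, the same adjusted over the list alone, his-24 by 5.27 ± 0.17 (adjusted p = 9.52e-05, and adjusted p = 0.444 with an estimated correlation), while the pseudogene beside the ribosomal RNA genes took a smaller share of counts in fed day 8 (1.78%) than in fed young (3.70%) libraries.

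Among the genes named in advance, fat-6 (-0.95 ± 0.07), acox-1.2 (-1.88 ± 0.07) and sod-3 (-1.5 ± 0.23) fell with age in fed animals, and nhr-49 (0.33 ± 0.05) and hlh-30 (0.45 ± 0.07) rose. The values of fat-5 (-0.34 ± 0.13, adjusted p = 0.0323) and hsp-6 (-0.36 ± 0.13, adjusted p = 0.0282) passed, and did not with RLE factors (adjusted p = 0.12 and adjusted p = 0.0818). Not called were lipl-4 (-0.11 ± 0.38), prx-5 (-0.18 ± 0.11), prx-10 (0.01 ± 0.11), daf-22 (-0.24 ± 0.15), ctl-2 (0.13 ± 0.09), drp-1 (0.14 ± 0.12) and fzo-1 (0.00 ± 0.09). Other scalings moved the median of all genes in this contrast by 0.11 (RLE) and 0.15 (upper quartile) on the log2 scale.

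In fasted animals, acs-2, icl-1, lipl-3 and fmo-2 were lower at day 8 than in young adults, the opposite side from fed animals. The values were -2.56 ± 0.10 for acs-2 (833 ± 21.8 CPM in young and 141 ± 19 CPM in day 8 animals, SD, n = 4), -2.99 ± 0.11 for icl-1, -3.47 ± 0.29 for lipl-3 and -1.52 ± 0.27 for fmo-2. Not all genes that fasting raised in young adults were lower. In fasted young and day 8 animals ptr-22 stood at 11.9 ± 0.519 and 32.45 ± 17.4 CPM, lipl-1 at 8.68 ± 0.661 and 22.03 ± 11.7 CPM and mtl-1 at 37.4 ± 1.55 and 39.04 ± 18.3 CPM, genes chosen for this comparison after their values were seen. Peroxins fell in 9 of 11 cases (9 adjusted over the list alone), prx-5 by 1.15 ± 0.11 and prx-10 by 0.34 ± 0.11. Camera gave adjusted p = 0.0206, and adjusted p = 0.22 with an estimated correlation. Peroxisomal enzymes fell in 17 of 21 cases and rose in 4, the same adjusted over the list alone, ctl-2 by 1.33 ± 0.09, daf-22 by 1.17 ± 0.15 and acox-1.2 by 0.72 ± 0.07. The list test gave adjusted p = 0.00349, and adjusted p = 0.22 with an estimated correlation. In total 5564 genes were higher and 6585 lower at day 8, a balance that turned with RLE (6349 and 6176) and upper quartile (6490 and 6178) factors, with DESeq2 (6453 and 6162) and with a filter at 5 CPM (4341 and 4248).

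Within the same limits of symbol, level and overlap, the largest rises in that comparison were those of clec-266 (7.81 ± 0.43), fbxb-66 (7.62 ± 0.54), ins-2 (7.55 ± 0.66), hmg-6 (7.34 ± 0.56), hch-1 (6.93 ± 0.54), dct-8 (6.91 ± 0.58), tbx-43 (6.69 ± 0.33), unc-39 (6.65 ± 0.51), ces-2 (6.49 ± 0.70) and zeel-1 (6.47 ± 0.38). The largest falls within them were those of msd-2 (-9.99 ± 0.78), msp-57 (-9.73 ± 0.92), col-139 (-9.67 ± 1.47), msp-79 (-9.63 ± 1.1), msp-10 (-9.49 ± 0.65), msrp-5 (-9.48 ± 0.55), msp-113 (-9.39 ± 0.82), msp-3 (-9.39 ± 0.75), msp-58 (-9.38 ± 0.70) and msp-64 (-9.37 ± 0.75). With DESeq2, 8 of 40 named genes in this contrast lost their call, where a missing adjusted p counts as no call. Sperm genes fell in 59 of 60 cases, and in 23 by DESeq2 (59 adjusted over the list alone; adjusted p = 6.36e-15, and adjusted p = 0.378 with an estimated correlation). Here too DESeq2 gave no adjusted p for 116 of all tested genes, which count as not called. Early embryonic genes rose in 36 of 42 cases and fell in 2 (37 and 2 adjusted over the list alone; adjusted p = 6.04e-11, and adjusted p = 0.000561 with an estimated correlation). Of the other genes named in advance, fat-5 (-1.42 ± 0.13), fat-6 (-1.41 ± 0.07), lipl-4 (-1.19 ± 0.37), hlh-30 (-0.93 ± 0.07), vit-2 (-1.42 ± 0.14), sod-3 (-1.19 ± 0.23) and hsp-6 (-0.41 ± 0.13) fell and drp-1 (0.40 ± 0.12) rose, while fat-7 (-0.37 ± 0.19), nhr-49 (-0.05 ± 0.05) and fzo-1 (0.08 ± 0.09) were not called. In both age comparisons the plate column followed age.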

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

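The tests of technical explanations and the other splits of the libraries were chosen after the results were seen. Chance alone marks about 1 in 20 groups when a library is compared with the other 3 of its group. Of 100 groups tested, 2 held such a library: fat-7 in fasted young adults (ratio 0.894) and prx-5 in fasted young adults (ratio 0.906).

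The fasting response differed between the ages for 2396 genes with a higher and 2254 with a lower young value. Differences (young minus day 8, log2) of genes named in advance were 6.42 for acs-2, 1.08 for fat-5, 0.46 for fat-6, -5.82 for fat-7, 7.25 for lipl-3, 5.18 for icl-1 and 0.38 for nhr-49. They were 1.38 for hlh-30, 0.98 for prx-5, 0.92 for daf-22, -1.16 for acox-1.2, 1.46 for ctl-2 and 8.29 for fmo-2. Among the largest within the limits for named genes were cyp-37B1 8.96, oac-14 6.67, ilys-3 6.64, cyp-32B1 6.41, clec-76 6.4, cpt-3 6.27 and ptr-22 6.11. On the other side were spp-23 -7.01, folt-2 -5.53, pho-13 -5.53, irg-8 -5.48, vit-1 -5.08, dod-19 -4.35, hrg-7 -4.16, vit-4 -4.14 and pcp-2 -4.08.

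Peroxisome and fat genes that differed were prx-6 1.08, prx-11 2.27, prx-2 0.93, acox-1.4 -2.97, acox-3 2.22, cpt-1 1.41, elo-5 -3.54, elo-6 -3.01 and elo-2 -3.12. Autophagy and lysosome genes were epg-9 1.71, atg-2 1.71, lgg-2 1.37, lgg-1 1.7, vha-11 -1.26 and vha-10 -1.03. Regulators and further metabolic genes were crtc-1 1.79, daf-2 1.31, ech-6 -2.01, hphd-1 -1.03, semo-1 1.64, nnt-1 4.87 and hil-1 2.75. Histones and collagens were his-8 -2.71, his-38 -2.45, his-40 -2.72, his-51 -2.67, col-95 1.79, col-143 -0.83 and col-101 -1.14.

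Of the lists, 26 passed for this difference with the preset correlation. With an estimated correlation autophagy alone passed (adjusted p = 0.0317), and the others ran from 0.0797 (lysosome) to 0.766 (oocyte). The values that follow are with the preset correlation. Adjusted p was 0.00509 for peroxins, 0.0418 for peroxisomal enzymes, 0.00127 for lipases, 0.0217 for fatty acid synthesis, 0.00488 for glycolysis, 0.00011 for autophagy and 4.09e-07 for lysosome. It was 0.000298 for nuclear and 0.0014 for mitochondrial genes of oxidative phosphorylation, 0.00739 for the endoplasmic reticulum stress list, 0.0297 for heat shock, 2.69e-06 for genes raised by DAF-16 and 0.00228 for pals genes. For germline and tissue lists it was 0.00727 (vitellogenins), 0.00368 (oocyte), 0.0117 (early embryo) and 0.00695 (basement membrane). Translation and the proteasome gave 0.000288 (mitochondrial ribosome), 0.000484 (translation factors) and 0.000504 (proteasome). The rest were histones 3.62e-05, neuropeptides 1.58e-05, propionate 0.000849, methionine 0.00549, metabolic regulators 0.000348 and flavin monooxygenases 0.041.

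Few genes were called with fasting at day 8, and 3 explanations were tested. A larger spread between day 8 libraries would leave the size of the response near that of young adults, and the slope of day 8 on young values was 0.0562. Day 8 fed animals could already stand at the fasted level, but genes with an unshifted fed level (475 higher, 160 lower) also responded little, with a largest ratio of day 8 to young medians of 0.064. That ratio leaves out genes whose fed level had shifted with age, such as fat-7, vit-1 and ptr-22, and cannot speak for them. Swapped labels could hide a response, and over all 35 splits of the day 8 libraries the largest slope was 0.066. Age itself, or the plate column or any other feature of the samples that goes with it, may be the cause and was not tested.

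Histones were higher in fasted day 8 animals, and the carry-over of RNA without a polyA tail could give this. With the share of the pseudogene beside the ribosomal RNA genes in the fit, the histone median was 0.49 (median SE 0.344), against 1.22 (0.332) without it, and called histones went from 9 to 0 in edgeR because the fold fell while the SE changed little, the list still passed camera, and all day 8 fasting calls went from 27 higher and 39 lower to 6 and 16. Within groups that share and the histone level had r = 0.812 (permutation p = 0.012, adjusted p = 0.018, n = 8) at day 8 and r = 0.743 (permutation p = 0.051, n = 8) in young adults, with libraries permuted within groups. The rank correlations were 0.881 (permutation p = 0.011) and 0.667 (permutation p = 0.11), and r without the 2 farthest libraries was 0.668 and 0.814. With this few libraries, carry-over cannot be told from a change in histone messages.

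Other splits of the libraries were used to ask whether chance can be excluded for the gene counts. The real split is included in each number of splits given as reaching the real value. For young fasting (7557, highest other 0 in edgeR), fed age (11675, highest other 0) and fasted age (12149, highest other 0) only the real split, 1 of 35, reached the real count. For day 8 fasting 5 of 35 splits gave as many (66, highest other 11889). The highest other split put libraries 1 and 2 against 3 and 4, which is structure among the libraries. Most of these splits leave same-numbered libraries together, which form pairs by the rule used but cannot be told from the sets. Among the 7 other splits that part all pairs the highest count was 0 in edgeR (99 against 514 with a block within each age), too few splits for a share under 0.05. For the age difference 2 of 100 splits gave as many calls (4650, highest other 4837), and 1 of 100 for the stricter set of young responders (4440, highest other 4432). The split with 4837 calls had a slope of 0.946 on the young response, so it kept the young labels and regrouped the day 8 libraries. The remaining splits regrouped the young libraries as well. These shares therefore cannot tell whether the difference depends on the day 8 labels. For the correlation of responses between ages 3 of 35 splits were as high (0.272, highest other 0.292). The 7 others that part all pairs, again too few, reached an absolute value of 0.172 (r = -0.172).

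Lists and families were split in the same way. For lists the real number was reached in 1 of 35 splits in young fasting (26, highest other 23) and 2 of 100 for the age difference (26, highest other 28). The split with 28 lists is the one that kept the young labels, so the share for the age difference has the limit given above. The real number was reached in 6 of 35 for fed age (27, highest other 30) and 9 of 35 for fasted age (24, highest other 31). The other splits that reached it exchange 1 library of each group and so keep part of the age difference. Splits that mix both groups evenly gave up to 18 lists in either comparison, so these shares cannot decide on chance. For day 8 fasting the real number was reached in 18 of 35 (19, highest other 27), and the 7 that part all pairs, too few for a share under 0.05, reached 17. For families it was reached in 8 of 35 for young fasting (29, highest other 36), 19 of 35 for day 8 fasting (21, highest other 59, and 14 among the 7 that part all pairs) and 55 of 100 for the age difference (24, highest other 61). In the age comparisons it was reached in 23 of 35 (fed, 38, highest other 54) and 15 of 35 (fasted, 43, highest other 63). For young fasting the other splits that reached the real number exchange 1 library of each group and keep much of the response. Splits that mix fed and fasted young libraries evenly gave up to 7 families, so this share cannot decide on chance. Chance cannot be excluded for the number of families in the age difference and the age comparisons. Nor can it be excluded for day 8 fasting, where the splits that part all pairs are too few for a share under 0.05.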

How the results depend on the processing

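Counts of calls depended on the fit, and the cause of each change was not tested. The replicate block within each age, the term for day 8 libraries 3 and 4, either set of day 8 libraries alone, summed libraries, the block with 8 libraries and voom were added after seeing the data. Young fasting gave 3790 higher and 3767 lower genes in the model described. It gave 2000 and 1201 at an absolute log2 change of at least 1, 6185 and 5865 with only the 8 libraries compared, and 6108 and 5817 with a block added to these. A block within each age gave 5799 and 5821, the term for libraries 3 and 4 gave 5965 and 5904, and voom gave 6356 and 5983. With day 8 libraries 1 and 2 only it was 6147 and 5744, and with 3 and 4 only 6251 and 5874. Day 8 fasting gave 27 higher and 39 lower genes. DESeq2 gave 98 and 129, the replicate block 15 higher, an absolute log2 change of at least 1 gave 10 lower, and only the 8 libraries compared gave 0 higher and 4 lower in edgeR. A block within each age gave 167 and 347, the term 224 and 614, libraries 1 and 2 only 97 and 231, and 3 and 4 only 369 and 1243. Voom gave 3 and 11, the block with 8 libraries 49 and 108, and summed libraries 7 and 29. Leaving out a library gave 10 (without fed day 8 library 1) to 43 (without fed 2) higher, and 22 (without fasted young 1) to 58 (without fasted day 8 library 4) lower. The age difference (2396 higher, 2254 lower) gave 1513 and 992 at an absolute log2 change of at least 1, 4204 and 4847 with a block within each age, and 4461 and 4937 with the term. It gave 3639 and 4336 with libraries 1 and 2 only, and 4476 and 4355 with 3 and 4 only. Age in fed animals (5491, 6184) gave 3172 and 4033 at an absolute log2 change of at least 1, and 4044 lower at a filter of 5 CPM. Age in fasted animals (5564, 6585) gave 2976 higher and 4248 lower in these settings. The balance of the age counts turned from more lower to more higher in some settings. With RLE factors it was 6346 higher and 5679 lower in fed and 6349 and 6176 in fasted animals, and with upper quartile factors 6781 and 5549, and 6490 and 6178. DESeq2, which changes the test as well, gave 6468 and 5664, and 6453 and 6162, and the filter at 5 CPM gave 4334 and 4044, and 4341 and 4248. In fed animals it also turned with no low-count filter (6423 and 5963), day 8 libraries 3 and 4 only (7278 and 7022) and summed libraries (5884 and 5658), and narrowly on leaving out day 8 fed library 3 (5862 and 5858) or 4 (5877 and 5862), or day 8 fasted library 3 (6117 and 5995) or 4 (6161 and 6014). TMM without germline, embryo and yolk genes did not turn it, at 5543 and 6236 in fed and 5659 and 6600 in fasted animals. Genes called in young but not day 8 animals (3767, 3736) numbered 1991 and 1192 at an absolute log2 change of at least 1, and 6351 and 5974 with voom. The higher ones numbered 5694 with the term, 6022 with libraries 1 and 2 only and 5741 with 3 and 4 only. The stricter set (2261, 2179) became 1281 and 878 at an absolute log2 change of at least 1, 3752 and 4486 with a block within each age, and 3895 and 4487 with the term. It was 3453 and 3727 with libraries 3 and 4 only, and 4048 lower with 1 and 2 only. With an estimated correlation the lists past the threshold (26, 19, 26, 27 and 24 for the 5 contrasts in the order young fasting, day 8 fasting, difference, fed age, fasted age) were 1, 1, 1, 2 and 1. The families (29, 21, 24, 38 and 43) were 1, 0, 1, 2 and 3 in camera. With fry the lists were 34, 11, 28, 41 and 44 in the same order of contrasts, and the families 87, 12, 61, 119 and 120. Families in day 8 fasting were 11 with libraries 1 and 2 only. The correlation between ages (0.272) and slope (0.056) were 0.305 and 0.051 at 5 CPM, 0.203 and 0.053 with a block within each age, 0.187 and 0.049 with the term, 0.124 and 0.062 with libraries 1 and 2 only, and 0.129 and 0.048 with 3 and 4 only. Over all tested genes they were 0.137 and 0.047, and over genes called at day 8 0.523 and 0.259. Leaving out a library gave r of 0.154 (without fasted day 8 library 4) to 0.318 (without fed young 4), and slopes of 0.039 (without fed day 8 library 1) to 0.073 (without fed 3). Among named genes, prx-10 reversed to -0.112 (adjusted p = 0.0119) in fed age with libraries 3 and 4 only. Over all alternatives named gene results were weaker in 8 of 3626 cases for young fasting, 176 of 1647 for day 8 fasting, 28 of 3166 for fed age and 8 of 1278 for fasted age. These cases include named genes called in neither fit, which cannot become weaker, so the share of calls lost is larger. With only the 8 libraries compared, 23 of 50 named genes lost their day 8 fasting call. List results were weaker in 54 of 650, 68 of 475, 58 of 650, 36 of 675 and 40 of 600 cases in the same order of contrasts.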

Other observations

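Families of genes that share a symbol prefix added to the lists. In fasted young adults nuclear hormone receptors (nhr) rose in 102 of 218 cases and fell in 14, with adjusted p = 8.73e-07, and adjusted p = 0.925 with an estimated correlation. The FMRFamide-like peptides (flp) rose in 22 of 30 cases (adjusted p = 4.93e-06, and adjusted p = 0.832 with an estimated correlation). Receptor guanylyl cyclases (gcy) rose in 14 of 30 cases and fell in 1 (adjusted p = 0.00882, and adjusted p = 0.961 with an estimated correlation). The sec genes of the secretory pathway fell in 10 of 19 cases (adjusted p = 4.23e-05, and adjusted p = 0.641 with an estimated correlation). Proton pump subunits (vha) fell in 17 of 20 cases and rose in 1, and passed both forms of the test (adjusted p = 6.75e-12, and adjusted p = 0.0204 with an estimated correlation).

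With age in fed animals the F-box family fbxb rose in 95 of 99 cases and fell in 1, with a median of 4.42 (adjusted p = 2.45e-24, and adjusted p = 0.0237 with an estimated correlation). The early zygotic sdz genes rose in 21 of 31 cases and fell in 2 (adjusted p = 2.2e-06, and adjusted p = 0.0188 with an estimated correlation). T-box genes (tbx) rose in 14 of 17 cases and fell in 1 (adjusted p = 0.000322, and adjusted p = 0.0553 with an estimated correlation). Skp1-related genes (skr) rose in 16 of 19 cases and fell in 1 (adjusted p = 3.67e-06, and adjusted p = 0.134 with an estimated correlation). All 31 msp genes fell, by a median of -8.02 (adjusted p = 1.13e-09, and adjusted p = 0.8 with an estimated correlation).

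Day 8 libraries 3 and 4 differed from libraries 1 and 2 in both feeding states, a comparison chosen after the result was seen. Of 16717 genes 5923 were higher and 5314 lower in 3 and 4. Collagens were higher in 103 of 154 cases and lower in 7 (median 1.63, adjusted p = 1.13e-06, and adjusted p = 0.532 with an estimated correlation). All 25 oocyte genes were lower (median -0.60, adjusted p = 2.31e-10, and adjusted p = 0.532 with an estimated correlation). Sperm genes were higher in 24 of 35 cases and lower in 2 (median 2.43, adjusted p = 0.0307, and adjusted p = 0.695 with an estimated correlation). Larval molting genes were higher in 13 of 15 cases and lower in 1 (median 1.17, camera adjusted p = 0.00197, and adjusted p = 0.532 with an estimated correlation). What separates these libraries is not stated in the labels.

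Fed day 8 animals were compared with the young fasting pattern, and the 2 tests of this were written before their results were seen. Higher both with fasting in young adults and with age in fed animals were 1425 genes (1166 if independent), 1820 were lower in both (1305), 1355 were higher with fasting and lower with age (1313), and 930 lower with fasting and higher with age (1159). The fed young libraries enter both comparisons and could give this alone, but with separate ones the covariance of log2 fold changes was 0.21, against 0.25 with shared ones and 0.027 in simulated unchanged groups. Correlations across genes were low, at r = 0.116 with shared libraries (0.276 in simulated unchanged groups), and with separate ones at r = 0.07 (rho 0.006) for day 8 libraries 1 and 2 and r = 0.12 (rho 0.081) for 3 and 4, so whether both sets carry the pattern cannot be told. An age effect on the same genes may be the cause and was not tested.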
